A study of Mus musculus with 8 samples.

How the data were processed

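Hippocampal RNA of 8 mice was measured on 1-colour Affymetrix mouse arrays, 1 array per mouse, with 4 mice of impaired and 4 of intact memory by the labels. Per the labels' protocols, 1 ng of total RNA was amplified to sense-strand cDNA with the WT Pico kit, fragmented and labelled with biotin. The deposited values are on the log2 scale, and per the submitters' processing notes the authors made them with RMA, which corrects background, normalizes arrays by quantiles and summarizes probes. The version of that software and the genome build are not given in the sources used here, so that no coordinates are printed. RMA fits all arrays together, which makes them comparable but compresses differences of dim genes towards the background. Amplification from 1 ng adds noise that a comparison of single arrays cannot separate from differences between mice.

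The table held 29129 probe sets, of which 22206 were targets, 5222 introns used as a negative control, 1324 exons used as a positive control, 23 antigenomic background probes and 354 other controls. Genes were named from the platform's probe table. There, 19572 target probe sets had 1 gene symbol, 0 had several and 2634 were not listed and are unnamed here. All 19572 matched a RefSeq gene of assembly GRCm38.p6 by Entrez identifier, and 0 symbols needed an update. That annotation served only for names and for the order of genes. Of 19505 genes, 55 had more than 1 probe set, and the probe set with the highest mean was used. The 25% of genes with the lowest mean over all arrays were left out, which set a floor of 5.33 and kept 14628 genes. Every column of the table belonged to 1 of the 8 mice, and no pair of arrays held identical values.

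Array quality was compared through the controls. The median of the intron controls was 5.24 to 5.34 and that of the exon controls 8.57 to 8.68 on the 8 arrays. RMA normalizes arrays by quantiles, which itself makes such medians alike. They therefore say little about signal over background before normalization. A hybridization control, BioB-5, stood at 11.2 on the array of impaired mouse 1 and at 9.55 to 9.90 on the others. The other BioB probe sets did not stand apart on that array. BioB-3 was 9.54, against 9.41 to 9.68 on the others, and BioB-M was 10.0, against 9.90 to 10.18. Scan dates and array batches were not used here, so that a batch effect could not be tested. The sex of the mice was not used either. The mean of the Y-linked genes spanned 0.27 over the arrays, less than the limit of 1 set for using it as a covariate, and that fit was therefore not run.

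Differences, impaired minus intact, were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists for cell types, neighbouring tissues and pathways were fixed before the data were examined, 54 in all, and 49 with at least 4 measured genes were tested with camera at a preset correlation of 0.01, against all other genes. Camera with an estimated correlation and the directional test fry were alternatives. A score per mouse, the mean deviation of a list's genes from their means over all mice, was tested by exact permutation over 70 relabellings, two-sided, with a smallest possible p of 0.0286. The lists of erythrocyte genes, microRNA loci, small nucleolar RNAs, Y-linked genes and mitochondrially encoded genes had too few measured genes, with 2, 3, 1, 0 and 0 kept, and were not tested.

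Genes were named by a rule fixed before the data were examined. In each direction, up to 12 genes were named with the smallest p among those with an unadjusted p under 0.01 and groups that do not overlap, leaving out symbols of predicted genes, olfactory and vomeronasal receptors and small RNAs. Of 88 such genes, 7 were left out for their symbol. Named were also the 4 members with the smallest p of each list that passed, members that passed when adjusted over their list alone, and App, Pla2g4e, Ttr, Gfap, Bdnf, Arc and the Y-linked genes in any case. Prnp, Xist and Ddx3y, named by the same rule, were not analysed here. Lists made by a symbol rule, such as ribosomal proteins, are given without members.

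The procedure was tested on simulated data with 200 of 14628 genes changed in the comparison of impaired with intact mice, at the spread of the real arrays. It recovered 50.4% of genes changed by 0.5, 95.3% of those changed by 1 and 99.5% of those changed by 2 on the log2 scale, and 4.68% of calls were false. Noise was drawn for each gene on its own, so that genes did not vary together between mice. With fewer changed genes the adjustment is stricter, so that these shares do not carry over to the real comparison. Lists of 20 genes shifted by 0.3 were called in 100% of cases. Unshifted lists were called in 2% at an unadjusted p of 0.05. When their members varied together between mice, by a shared deviation with an SD of 0.2, 59% were called, against 5.5% with an estimated correlation. The preset correlation therefore makes false calls for lists whose genes vary together, at a rate that depends on how closely they do. Estimated correlations of the 8 real lists that passed ran from 0.16 (interferon response) to 0.97 (thalamus). The 59% is thus not the rate of any given list.

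The alternatives fixed beforehand were no filter on dim genes, a filter on 50% of genes, quantile normalization, median centring, the replicate number as a block, an intensity trend with a robust prior, array weights, the choroid plexus score as a covariate, 1 surrogate variable as a covariate (wsva of limma, in place of the planned sva package), the mean of a gene's probe sets, all probe sets tested separately, both other list tests and leaving out each mouse. The thalamus score, alone and with the plexus score, was added as a covariate after seeing the data, as was camera with an estimated correlation and both scores. Profiles close to that of Pla2g4e were also looked through before any test of its chromosomal neighbours was written. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.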

Results

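The study asked which differences in hippocampal gene expression go with memory loss among aged mice that carry an amyloid precursor protein transgene. Hippocampi were taken from 8 mice of the strain B6.Cg-Tg(APPswe)E1-2Dbo/J, aged 18 to 20 months, after the Morris water maze, a test in which a mouse learns the place of a platform hidden under water. By the labels, 4 mice had impaired memory and 4 had intact memory, and each mouse gave 1 array. Expression is given on the log2 scale after robust multi-array averaging (RMA), so a difference of 1 is a doubling. The median over the 14628 genes tested lay between 7.75 and 7.79 on the 8 arrays, and pairs of arrays correlated across genes at 0.979 to 0.989. The number of arrays limits the precision: the median standard error of a difference between the groups was 0.105.

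In the mice with impaired memory, the gene with the smallest p was Scg5, which encodes the secretory granule protein 7B2, a chaperone of prohormone convertase 2. Its expression was 10.45 ± 0.16 (SD, n = 4) in the impaired group and 11.19 ± 0.17 (SD, n = 4) in the intact group, which is 1.67-fold lower in the impaired group. Frzb, a secreted antagonist of Wnt signalling, was 1.55-fold lower, and Tbx3, a T-box transcription factor, was 1.40-fold lower. Among the genes with higher values in the impaired group were Osmr, the receptor for the cytokine oncostatin M (1.47-fold), Zfp36, an RNA-binding protein that speeds the decay of cytokine mRNAs (1.46-fold), and the interferon-induced gene Ifit3 (1.34-fold). For each of these 6 genes the 4 impaired values did not overlap the 4 intact values. The genes were chosen for this, so that it is no evidence of a difference. None of the genes tested passed an adjusted p of 0.05.

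The log2 difference of Scg5, impaired minus intact, was -0.74 with a standard error of 0.11 (limma, adjusted p = 0.267). With an intensity trend and a robust prior in limma, Scg5 alone passed (adjusted p = 0.00958), while its adjusted p ranged from 0.00958 to 0.999 over all settings tried. Frzb differed by -0.64 (standard error 0.15) and Tbx3 by -0.48 (standard error 0.088), with adjusted p of 0.961 and 0.604. The other genes with lower values and the smallest p in the impaired group were Nfatc4, a calcium-dependent transcription factor, Snrpe, a core protein of spliceosomal particles, Rsph9, a radial spoke protein of motile cilia, the adaptor Dok2, Slx4ip, Zfp689, Gmeb2, Eef1akmt3 and Strip2. Their log2 differences ran from -0.51 for Slx4ip to -0.35 for Eef1akmt3, and for each the groups did not overlap, as the rule of choice required.

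Of the genes with higher values and the smallest p, Osmr differed by 0.55 with a standard error of 0.12 (limma, adjusted p = 0.961). Zfp36 differed by 0.55 (standard error 0.11), Pxylp1 by 0.54 (standard error 0.095) and Xlr3a by 0.53 (standard error 0.082), with adjusted p of 0.961, 0.595 and 0.267. Xlr3a belongs to a family of near-identical X-linked copies, and H2-T3 and Ifit3 also have close relatives, so that the assignment of their signal to 1 gene is uncertain. Fut4, a fucosyltransferase, Hopx, a homeodomain protein, Ciao2a, a factor of cytosolic iron-sulfur assembly, Foxr2, Hoxb7, H2-T3 and Doxl2 made up the rest, with differences from 0.27 for Hopx to 0.49 for Ciao2a. Hopx stood at 8.33 ± 0.0074 (SD, n = 4) in the impaired group and 8.06 ± 0.061 (SD, n = 4) in the intact group. Of these 24 genes, 8 had a mean below 6.30, the 75th percentile of the probe sets for introns that serve as a background on this array. They were Xlr3a, Pxylp1, Fut4, Foxr2, Doxl2, Nfatc4, Slx4ip and Dok2, and of all genes tested 18.0% lay below that level. The 95th percentile of the introns was 7.92, and only Scg5 and Hopx of the 24 had a mean above it.

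Pla2g4e, a cytosolic phospholipase A2 that also makes precursors of endocannabinoid-like lipids, had the largest difference among the named genes. It was 1.96-fold lower in the impaired group, at 7.04 ± 0.53 (SD, n = 4) against 8.01 ± 0.26 (SD, n = 4) in the intact group. Impaired mice 1, 2 and 3 had values of 6.67, 6.91 and 6.77, while impaired mouse 4 had 7.82, within the intact values of 8.11, 7.80, 8.33 and 7.80. The log2 difference was -0.97 with a standard error of 0.23 (limma, adjusted p = 0.961), and without impaired mouse 4 it was -1.23 (adjusted p = 0.107, in a range of 0.107 to 1.00 over all settings). Adjusted over the list alone, Pla2g4e passed among 11 measured phospholipases A2, but the gene was put on the list and among the genes always named from prior knowledge of the study, so that this count is not independent evidence. Of these 11 phospholipases, 9 had lower values in the impaired group (camera, adjusted p = 0.145), and the list's score gave an exact permutation p of 0.0286, the smallest that 70 relabellings allow, with an adjusted p of 0.869. The list test and the score include Pla2g4e, so that they are not independent evidence either, and neither was run without it. The mean difference of the list was -0.14 and the median -0.092.

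**Figure D1:**
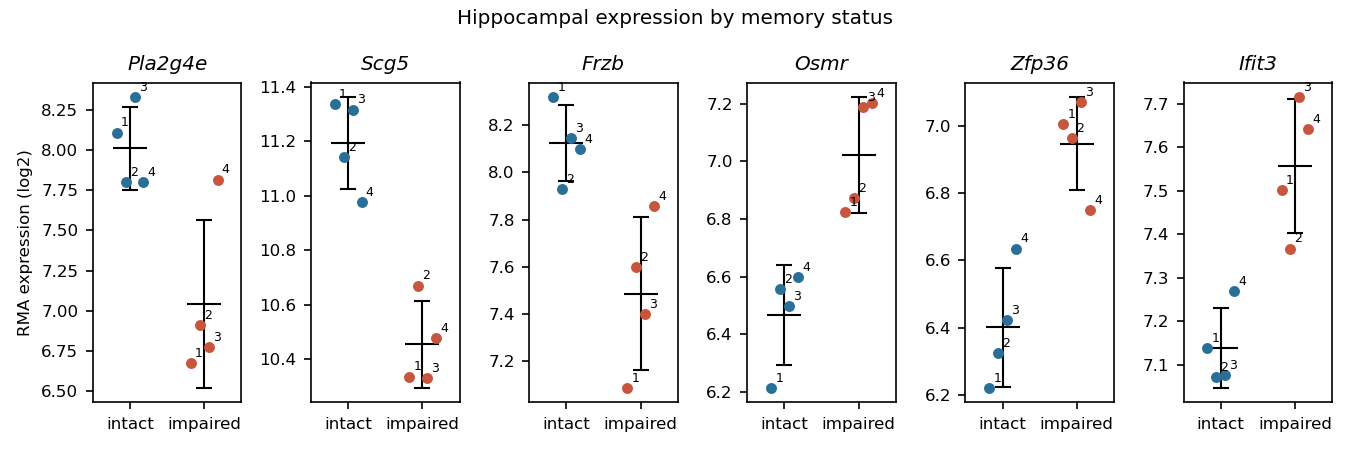
Expression (log2, RMA) of 6 genes in mice with intact and impaired memory, 1 point per mouse with its replicate number, with the mean (horizontal line) and SD (bars, n = 4). Scg5, Frzb, Osmr, Zfp36 and Ifit3 were chosen for groups that do not overlap. Pla2g4e of impaired mouse 4, at 7.82, lies among the intact values. None of the 6 genes passed the adjustment over all genes.

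App itself, whose probes may read the mouse gene and the transgene alike, did not differ between the groups by more than their spread. It stood at 12.64 ± 0.058 (SD, n = 4) in the impaired group and 12.63 ± 0.030 (SD, n = 4) in the intact group, and the 95% interval of the log2 difference ran from -0.15 to 0.17. Gfap, the intermediate filament of astrocytes, differed by 0.17 (standard error 0.16), and the activity-dependent genes Bdnf and Arc by 0.20 (standard error 0.12) and 0.27 (standard error 0.16). Over all settings Gfap ran from 0.061, without intact mouse 3, to 0.30. Bdnf ran from 0.093 to 0.34 and Arc from 0.11 to 0.37, both lowest without impaired mouse 1. Ttr, the thyroid hormone carrier made by the choroid plexus, differed by -0.65 with a standard error of 0.81, and it was 9.79 in impaired mouse 3 and 10.6 in intact mouse 3 but at least 12.3 in the other mice. The Y-linked genes Eif2s3y, Kdm5d and Uty had values of 2.23 to 3.98 on all 8 arrays, below the level of 5.33 that a gene needed to be tested. Antigenomic background probes had medians of 3.85 to 4.06 on these arrays. No array thus showed a clear Y-linked signal above background, and these genes gave no sign of a sex difference between the groups.

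Over all 14628 genes, limma called 0 at an adjusted p under 0.05, and 685 had an unadjusted p under 0.05, where chance gives 731.4. At an unadjusted p under 0.01 there were 108 genes, 51 higher and 57 lower in the impaired group, where chance gives 146.28. Without impaired mouse 4 there were 202 such genes, the highest count among the fits that left out a mouse, and none passed the adjustment. Other splits of the 8 mice into 4 and 4 gave up to 401 such genes. The groups did not overlap for 377 genes, or 2.58%, where chance gives 2.86%.

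Among the gene groups fixed beforehand, genes that respond to glucocorticoids were higher as a group in the impaired mice, in 13 of 14 measured members, by 0.21 on average (camera, adjusted p = 0.000335, and 0.972 with an estimated correlation). The adjustment gave nearly every list this same 0.972. Before it, camera with an estimated correlation gave p of 0.110 here, and from 0.067 (interferon response) to 0.385 (thalamus) over the 8 lists that passed. Of the 49 lists, 0 had such a p under 0.05. Sgk1, a kinase induced by glucocorticoids, stood at 9.30 ± 0.36 (SD, n = 4) in the impaired group and 8.84 ± 0.20 (SD, n = 4) in the intact group, and the clock gene Per1 at 9.11 ± 0.13 and 8.86 ± 0.14. Pdk4, a kinase that inhibits pyruvate dehydrogenase, differed by 0.31 (standard error 0.14) and Nfkbia, the inhibitor of NF-kB, by 0.33 (standard error 0.15). Over all settings Pdk4 ran from 0.096 to 0.41 and Nfkbia from 0.16, without impaired mouse 2, to 0.43. No member passed, over all genes or adjusted over the list alone. With the preset correlation, the call held without each mouse in turn, but the mean difference was 0.12 (adjusted p = 0.0388) without impaired mouse 2, which had the highest score, 0.38. The call was lost with both the plexus and thalamus scores as covariates, a setting added after seeing the data and given below.

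Genes of the interferon response were also higher as a group, in 11 of 13 members, by 0.13 on average (camera, adjusted p = 0.00354, and 0.972 with an estimated correlation). Ifit3 passed when adjusted over the list alone (limma, adjusted p = 0.0155) but not over all genes (adjusted p = 0.961). Adjusting over 1 list does not allow for the 49 lists searched. Olfactory and vomeronasal receptors, a list that did not pass camera (adjusted p = 0.347), had 2 such members. Usp18, the protease that removes ISG15, differed by 0.39 (standard error 0.14), and Oasl2 and Ifit2 by 0.36 (standard errors 0.19 and 0.19). The 2 lower members were Bst2, at -0.51 (standard error 0.38), and Isg15, at -0.014 (standard error 0.16). Impaired mouse 3 had the highest score, 0.32, and without it the mean difference was 0.049 (adjusted p = 0.117). Reactive astrocyte genes were higher in 15 of 20 members, by 0.12 on average (camera, adjusted p = 0.0108, and 0.972 with an estimated correlation). Osmr passed when adjusted over that list alone (limma, adjusted p = 0.0162) but not over all genes (adjusted p = 0.961). Steap4, the complement gene C4b and the hyaluronan receptor Cd44 differed by 0.32, 0.29 and 0.21. Without impaired mouse 3, impaired mouse 4 or intact mouse 3, the mean difference of the astrocyte list was 0.040, 0.094 and 0.065 (adjusted p = 0.363, 0.0921 and 0.173), and without impaired mouse 2 it was 0.18 (adjusted p = 0.000812).

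Immediate early genes, which neurons induce within minutes of activity, were higher as a group in the impaired mice, in 19 of 23 members, by 0.13 on average (camera, adjusted p = 0.00315, and 0.972 with an estimated correlation). Dusp1 and Dusp5, phosphatases of MAP kinases, differed by 0.35 (standard error 0.18) and 0.22 (standard error 0.11), and the neuronal transcription factor Npas4 by 0.43 (standard error 0.24). The list rested on impaired mouse 1, with a score of 0.42, in which Npas4 stood at 7.94 against at most 7.02 in the other 7 mice. Without impaired mouse 1 the mean difference was 0.0079 (adjusted p = 0.889). Meningeal fibroblast markers were higher in 9 of 10 members, by 0.19 on average (camera, adjusted p = 0.00600, and 0.972 with an estimated correlation), among them the transporters Slc22a6 and Slc6a13 with 0.50 (standard error 0.16) and 0.32 (standard error 0.16), the proteoglycan Lum with 0.34 and the collagen Col1a1 with 0.13. Without impaired mouse 4 or intact mouse 1 the mean difference of this list was 0.12 in both cases (adjusted p = 0.197 and 0.0645). Ribosomal protein genes were lower in 47 of 58 members, by -0.053 on average (camera, adjusted p = 0.0108, and 0.972 with an estimated correlation), with an adjusted p of 0.255 after quantile normalization (mean -0.020). Their mean was -0.031, -0.048 and -0.046 without impaired mouse 2, intact mouse 3 or intact mouse 4 (adjusted p = 0.364, 0.0826 and 0.151) and -0.086 without impaired mouse 4 (adjusted p = 0.000336).

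Markers of tissue that borders the hippocampus differed widely between single mice, and the difference of their scores between the groups did not pass an exact permutation test (p = 0.343 for the choroid plexus and 0.429 for the thalamus). All 14 choroid plexus markers had lower values in the impaired group, by -0.46 on average (camera, adjusted p = 0.00354, and 0.972 with an estimated correlation), among them Kl, F5, Steap1 and Sostdc1 with -0.66, -0.75, -0.67 and -0.52. All 12 thalamus markers had higher values, by 0.35 on average (camera, adjusted p = 0.0150, and 0.972 with an estimated correlation), among them Shox2, Tcf7l2, Ramp3 and Prkcd with 0.79, 0.51, 0.34 and 0.44. With the plexus score as a covariate, a setting fixed beforehand, their mean difference was 0.54 (camera, preset correlation, adjusted p = 0.000103). The score of the thalamus list was -1.42 in intact mouse 3 and lay between -0.19 and 0.48 in the other 7 mice, and without intact mouse 3 the mean difference was -0.069 (adjusted p = 0.683). The thalamus list also did not pass without impaired mouse 2 or impaired mouse 3, at 0.25 in both cases (adjusted p = 0.147 and 0.180), and its mean was 0.56 and 0.55 without intact mouse 2 or intact mouse 4 (adjusted p = 0.000253 and 0.000299). The plexus score was -0.95 in impaired mouse 3 and -0.92 in intact mouse 3, and without impaired mouse 2, impaired mouse 3, intact mouse 1 or intact mouse 4 the mean difference was -0.40, -0.22, -0.24 and -0.40 (adjusted p = 0.0816, 0.180, 0.203 and 0.0523). Without intact mouse 3 it was -0.84 (adjusted p = 1.92e-14). With both scores as covariates, a setting added after seeing the data, the glucocorticoid, interferon, reactive astrocyte and ribosomal lists no longer passed, with means of 0.10, 0.040, 0.041 and -0.033 (adjusted p = 0.126, 0.402, 0.529 and 0.442). In that setting the immediate early genes passed with a mean of 0.23 (adjusted p = 1.34e-08) and the meningeal fibroblast markers with 0.21 (adjusted p = 0.0307), and markers of endothelial cells, oligodendrocytes and striatum passed as lower (adjusted p = 0.000248, 1.34e-08 and 0.0307). None of these 5 lists passed with both scores and an estimated correlation (adjusted p = 0.993 for each), and without covariates the immediate early genes rested on impaired mouse 1 (mean 0.0079, adjusted p = 0.889 without it). The first and second principal components took 23.2% and 20.2% of the variance, and their 40 leading genes held 10 thalamus markers and 11 plexus markers.

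**Figure D2:**
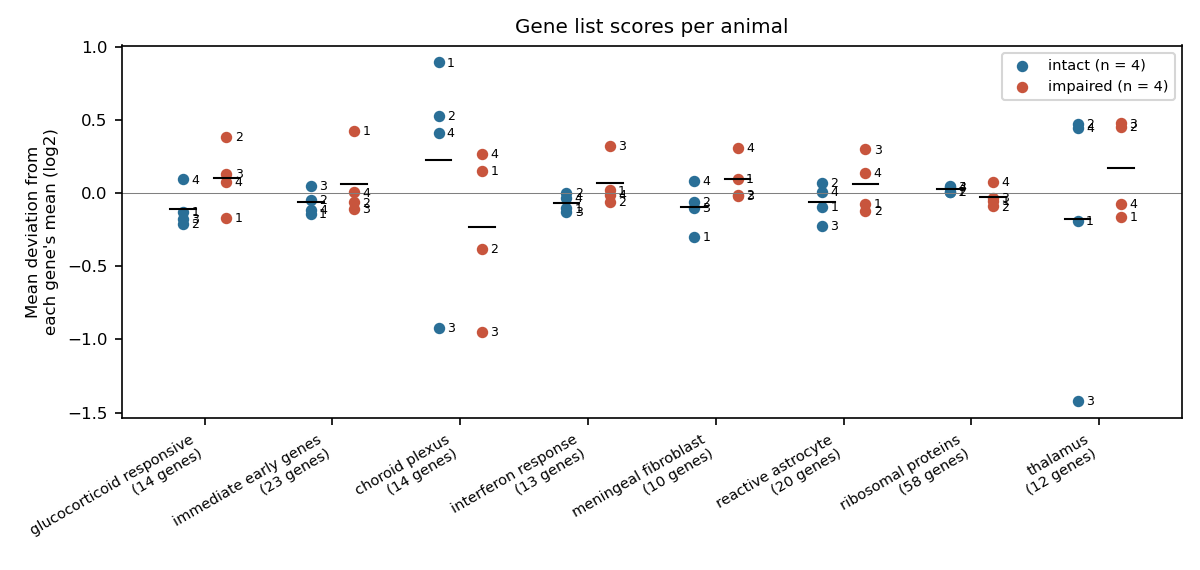
Score of each of the 8 gene lists that passed camera with a preset correlation, as the mean deviation (log2) of the list's genes from their means over the 8 mice, with 1 point per mouse, its replicate number, and the group mean as a line (n = 4 per group). The thalamus score of intact mouse 3, at -1.42, and the immediate early gene score of impaired mouse 1, at 0.42, stand apart from the other mice.

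The remaining 41 of 49 lists did not pass, with adjusted p of 0.0518 or more. Markers of endothelial cells were lower in 11 of 12 members (camera, adjusted p = 0.0518) and those of oligodendrocytes in 11 of 11 (adjusted p = 0.0884). With the preset correlation, these lists passed as lower in 10 and 7 of 19 other settings, with smallest adjusted p of 0.000248 and 1.34e-08. Striatum markers passed as lower in 6 of them and ependymal markers in 2, and genes of complement, of lysosome and autophagy and of olfactory and vomeronasal receptors passed as higher in 1 each (smallest adjusted p = 0.00510, 0.0207, 0.0243, 0.0243 and 0.0424). All 7 of these lists had an adjusted p of 0.972 with an estimated correlation. Markers of CA1 and CA3 pyramidal neurons, dentate granule cells and GABAergic interneurons differed by 0.0098, -0.082, -0.0041 and 0.027 on average, with adjusted p from 0.355 to 0.953. Genes of glutamate receptors and the postsynaptic density differed by -0.022 and those of presynaptic vesicle release by -0.038, the latter lower in 15 of 18 members (adjusted p = 0.785 and 0.355). Disease-associated microglia genes were higher in 10 members and lower in 10, by 0.091 on average (adjusted p = 0.174, and 0.972 with an estimated correlation), and 3 members were higher and 0 lower at an unadjusted p under 0.05. With the preset correlation, this list passed as higher without impaired mouse 1, impaired mouse 2 or intact mouse 2 (adjusted p = 0.0320, 0.0388 and 0.0185). Homeostatic microglia markers differed by 0.041 (adjusted p = 0.785), and genes of APP processing by -0.029 (adjusted p = 0.785). The mean, the median and the test differed in sign for 11 lists, none of which passed. With exact permutation of the scores per mouse, no list passed, and the smallest adjusted p was 0.869. As no p can fall below 0.0286, a list could pass this adjustment only if most of the 49 reached that minimum. The adjusted values therefore say little about any single list. Before adjustment, the exact permutation p of the 8 lists that passed camera ran from 0.143 (meningeal fibroblast) to 0.457 (immediate early genes). For the glucocorticoid list it was 0.2, so that none of these scores clearly separated the groups. Of the 49 lists, only 1, the phospholipases A2, had such a p under 0.05.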

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

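The tests of how markers of 1 tissue vary together were chosen after the lists' results had been seen, while the test of Ttr against the other plexus markers was set before its result. A value was singled out where 1 of 4 mice of a group lay far from the other 3, by Dixon's criterion. Over 126 groups of 4 mice there were 10 such values, where chance gives about 6.3.

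Ttr was 10.6 in intact mouse 3, against 13.3 to 13.7 in the other intact mice. Gfap was 10.5 in the same mouse, against 10.9 to 11.0. Sgk1 was 8.76 in impaired mouse 1, below 9.43 to 9.52 in the other impaired mice, and Pdk4 was 8.05 in intact mouse 4, above 7.65 to 7.69. Lum was 6.33 in impaired mouse 1, above 5.70 to 5.78, and Doxl2 was 6.23 in that mouse, above 5.90 to 5.94. Bdnf was 7.94 in intact mouse 2, below 8.15 to 8.18, and H2-T3 was 6.46 in that mouse, above 6.24 to 6.26. Nfatc4 was 5.41 in impaired mouse 2, below 5.58 to 5.61, and Slx4ip was 6.58 in intact mouse 4, above 6.32 to 6.36.

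The lower choroid plexus and higher thalamus values of the impaired group were weighed against unequal amounts of neighbouring tissue in the dissections. Within groups, the 14 plexus markers varied together with a median pairwise correlation of 0.898, and the 12 thalamus markers with 0.968, where the 95th percentiles of random lists of the same size were 0.126 and 0.154; these are correlations of residuals over 8 mice, and 0 of the markers stand in another list, though how many the hippocampus itself expresses was not counted. With the mean of the other plexus markers as a covariate, Ttr differed by 0.35 (standard error 0.32), against -0.65 without it, which argues against a fall of Ttr of its own. Tissue carried along in the dissection is therefore a candidate explanation for how both lists vary between mice. A difference of the plexus or thalamus with memory passed camera with the preset correlation (adjusted p = 0.00354 and 0.0150) but not exact permutation of the scores (p = 0.343 and 0.429), so that it was not established, and its cause stays open.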

How the results depend on the processing

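The thalamus score and both tissue scores as covariates, the latter also with an estimated correlation, were added after seeing the data; all other settings were fixed before. Signal over background limits dim genes, and the filter decides how many of them are tested. The count of genes past the adjustment was 0 in every setting run, leaving out each mouse included, except for 1 (Scg5) with an intensity trend and robust prior. At an unadjusted p under 0.01 the count was 189 without the filter, with more genes tested (chance 195.05), and 72 to 202 without 1 mouse, highest without impaired mouse 4; the cause of the latter was not tested. Lists past the threshold numbered 6 to 11 without 1 mouse, 5 with both tissue scores, of which 2 were among the original 8, and 0 with an estimated correlation (smallest adjusted p 0.972, and 0.993 with both scores) or with fry (0.581), which allow for genes that vary together. Over all genes the replicate numbers did not pair the mice: same-numbered mice deviated together with r of 0.028, 0.033, -0.048 and -0.10, and 0 of 8 mice correlated best with their own number. For single lists a pairing is not excluded. Plexus scores of same-numbered impaired and intact mice were 0.15 and 0.89, -0.38 and 0.53, -0.95 and -0.92, and 0.27 and 0.41. With the replicate block, 0 genes, 103 genes at p under 0.01 and 11 lists were called. The plexus list then had an adjusted p of 1.85e-10 (camera, preset correlation), without allowance for markers that vary together. Of 1074 refits of 55 named genes, 1061 kept direction and side of the threshold, 1 passed and 12 turned sign, none of them past the threshold. No named gene had passed in the main setting, so that keeping the side of the threshold shows little. The 24 genes named by smallest p were chosen for groups that do not overlap, so that leaving out 1 mouse could not turn their sign. App turned to -0.0073 with the plexus score, -0.0033 with the thalamus score and -0.035 with both, and ran from -0.015 to 0.030 without 1 mouse, below 0 without impaired mouse 2, impaired mouse 3 (-0.0019) or intact mouse 1 (-0.0073). Ttr turned to 0.32 with the plexus score and 0.40 with both scores, and ran from -1.38 to 0.11 without 1 mouse, highest without impaired mouse 3. Tcf7l2 ran from -0.033 to 0.85, Ramp3 from -0.043 to 0.54, Prkcd from -0.064 to 0.71 and the thalamus list from -0.069 to 0.56, each lowest without intact mouse 3. Of 169 refits of the lists, 121 kept their call, 47 lost it and 1 reversed. Besides the losses without 1 mouse, with both scores or with the other list tests, the adjusted p was 0.0622 for meningeal fibroblasts without the filter, 0.121 for reactive astrocytes with 50% of genes left out, 0.152 and 0.0858 for reactive astrocytes and ribosomal proteins with the thalamus score, and 0.255 for ribosomal proteins after quantile normalization. The cause was not tested. A list was not refitted with its own score as a covariate or with the robust prior, which camera does not use; the interferon list, with 3 of its genes left, gave no value with 50% of genes left out; and the sex covariate was not run.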

Other observations

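The tests of Pla2g4e against tissue scores and against its 40 nearest genes were chosen after the results they bear on had been seen, while those of genes farther away, of close pairs of genes and of other splits were set before. Several genes differed far more between single mice than between the groups. These were chosen after their values were seen. Masp2, a protease of the lectin pathway of complement, was 6.20 in impaired mouse 4 and 6.30 in intact mouse 4 and 8.04 to 9.09 in the other 6 mice, with a difference between the groups of 0.091 (limma, unadjusted p = 0.885). H2-T23, a nonclassical class I histocompatibility gene with close relatives, was 4.79 in impaired mouse 2 and 5.13 in intact mouse 3 and 6.45 to 7.17 in the others. Lcn2, a lipocalin of acute inflammation, was 8.03 in impaired mouse 3 and 5.54 in impaired mouse 1. Zfp605 was 6.99 in intact mouse 2 and 8.40 to 8.93 in the other 7 mice.

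The lower Pla2g4e of the impaired group was weighed against tissue in the dissection and an inherited chromosome segment: with the plexus score as a covariate the difference was -0.96 (standard error 0.26), and with the thalamus score -0.86 (standard error 0.22), 99.1% and 88.7% of the value without them. With both scores the difference was -0.74, the smallest in any refit, so that both together took up more of it than either alone. These values argue against either tissue as the whole cause. The segment was thought of only after 2 of the 10 profiles closest to Pla2g4e over all mice proved to be those of Ganc and Snap23, 3 and 6 places away on chromosome 2, which 0.171% of all genes match, but a value that gave the idea is no test of it. Ganc and Snap23 had lower values in the impaired group too, by -0.37 (standard error 0.11) and -0.39 (standard error 0.098), with impaired mouse 4 at 7.80 and 9.71 against 7.42 to 7.47 and 9.34 to 9.38 in the other impaired mice and 7.75 to 8.08 and 9.77 to 9.93 in the intact mice. On residuals within groups, 1 of the 40 nearest genes (Ganc) was among the 147 closest profiles, where chance gives 0.402 (permutation p = 0.337) and Snap23 ranked 161, and 3 of 160 genes farther away were, where chance gives 1.61 (p = 0.188); a bound of at most 1 near gene, first written against the idea, lies above chance and excludes nothing. An inherited segment may thus be held only as a hypothesis that these counts neither bear out nor exclude, and a difference tied to memory itself stays open too.

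The genes with an unadjusted p under 0.01 were asked whether they lie together on chromosomes, as inherited segments would have it. There were 11 pairs within 10 places of each other, where permuted positions gave 7.81 ± 2.79 (mean and SD, permutation p = 0.161), so that the data did not decide.

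Every split of the 8 mice into 4 and 4 was fitted, 35 in all. For genes past the adjustment the real count was 0, which all 35 splits reach by construction, so that this count tests nothing; the highest other was 1. For genes at an unadjusted p under 0.01, 21 of 35 splits gave at least the real 108, and the highest other was 401. For lists past the threshold, 19 of 35 gave at least the real 8, and the highest other was 18. Chance was not excluded for the genes at an unadjusted p under 0.01 or for the lists. The split with 401 genes set impaired mice 1 and 4 and intact mice 1 and 3 against the other 4, and the next, with 310, set impaired mice 1, 2 and 3 and intact mouse 4 apart. Counts that far above the real one point to a structure of the samples. The 4 mice first named had thalamus scores of -0.16, -0.074, -0.19 and -1.42, against 0.45 to 0.48 in the others, and the 4 lowest values on the first principal component, while the split with 310 set 3 of the 4 highest on each measure together with impaired mouse 1. This match was seen after the counts, and no test tied the counts to either measure.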
